A study of Caenorhabditis elegans with 2 samples.

How the data were processed

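Chromatin immunoprecipitation followed by sequencing was used to map LIN-15B, a nuclear protein of the nematode Caenorhabditis elegans, in whole L3 larvae. The worms, strain OP184, carry an integrated transgene for LIN-15B fused to eGFP in an unc-119 mutant background, per the labels. There were 2 biological replicates of 1 group and no second group, so no condition could be compared with another. Per the labels, the fragment size range was 150 to 350 bp.

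Per the deposited text records, peaks were called in each replicate against a control, in the pooled alignments of both replicates, and then thresholded by the irreproducible discovery rate (IDR), in builds ce10 and ce11. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The signal of each peak is the authors' own deposited value on a scale that is not given. It was used only to rank and describe peaks within a list and to set the signals of the replicates side by side at the same peaks. The q-value of each peak is the deposited −log10 value of the authors. It reached its ceiling of 3.96 in every peak of the IDR list, so it could not rank them. Summit positions were taken from the deposited lists. Of the ce11 IDR peaks, 64.6% shared a width of 310 bp, so their summits are the middles of fixed intervals.

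Read counts are not given in these lists and the sequencing depth is unknown. The number of peaks limits the precision instead. Intervals are exact 95% Clopper-Pearson intervals, and where a share was 0 the limit is 3 counts of the total. Both cover counting error only.

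The following was fixed before the data were examined: the ce11 IDR list as the main list, the tests, 18 gene lists, 9 sequence motifs, the rule for named genes and most of the alternatives. The genome was WBcel235, the same assembly as ce11, with Ensembl annotation release 115. All positions are 1-based. A promoter window ran from 500 bp upstream to 200 bp downstream of each annotated 5' end of a protein-coding transcript, and a gene was called bound if a summit lay in its window. Gene list members were matched by symbol, and 1 of the meiosis list, msh-4, had no match among protein-coding genes and was left out, as the RefSeq annotation gives that symbol to a pseudogene. Many C. elegans transcripts are trans-spliced, so an annotated 5' end can lie downstream of the site of initiation. Genes that share a window can be called bound by the same peak.

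Locations and replicate overlap (at least 1 bp) were tested against 1000 circular shifts of the peaks within each chromosome, with seed 20 and two-sided p-values of which 0.000999 is the smallest they can give. Shares of bound genes were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. Motifs and all 2080 6-mers, read on both strands, were counted within 50 bp of each summit and in a window centred 300 bp to one side. They were compared by exact two-sided sign tests, adjusted within each family. Ratios of windows had 0.5 added to both counts.

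Named genes were those with 1 of the 20 highest peaks in the promoter window, up to 4 bound members with the highest signal per list (all bound members of lists under 20 genes), and lin-15B, lin-15A and unc-119. Unbound members could be named for the first 4 lists. Genes named outside the rule are marked as such.

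The centre of a chromosome was the middle of its length and the arms the outer parts, of equal total length. The alternatives were a stricter list of the 1665 peaks with the highest signal, promoter windows of 1000 and 200 bp upstream, the list of each replicate alone, peak intervals, other overlap rules, the ce10 lists, other backgrounds, genes with overlapping windows counted once, and other motif windows. A lenient list of 4585 pooled peaks at the q-value ceiling, shuffled and unbound-promoter motif controls, and all alternatives for feature classes and transgene loci were added after seeing the data.

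The code was tested on simulated data. For the gene lists, 5.75% of 400 random lists over 19973 genes had a p under 0.05, 0 of these lists passed the adjusted threshold, and 100% of 50 planted lists of genes bound at 50% did. For the X chromosome over the same genes, 6% of 200 sets with no difference had a p under 0.05, and a planted deficit of 7 points was found as -7.09 points. For the promoter share, 7.5% of 40 sets of 3000 random summits had a p under 0.05, and 58.5% was found where 58.2% was planted. For replicate agreement, 80.4% was found where 80.0% of 3000 peaks were shared. Among 2080 6-mers in random windows, 1 was called, and a planted 6-mer ranked first. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.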

Results

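LIN-15B belongs to the synMuv B group of C. elegans proteins, known for roles in vulval development and in repression of germline genes in somatic tissue. Its eGFP fusion was profiled in 2 biological replicates of whole L3 larvae. The labels name no other condition, so the comparisons are between replicates, between parts of the genome and between groups of genes. The sequencing depth is unknown, and the number of peaks or genes limits the precision of each share.

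The IDR list held 3331 peaks in ce11. They were the 3331 peaks with the highest signal among the 30000 of the pooled list. The lists of replicates 1 and 2 held 24760 and 27552 entries, deposited as peaks and background for the thresholding. Of the 3331 highest peaks of replicate 1, 2734 (82.1%) overlapped one of the 3331 highest of replicate 2, against a mean of 2.02% and a highest value of 2.85% over circular shifts (permutation p = 0.000999, the smallest they can give). The 100 and the 500 highest peaks of replicate 1 were all found there. Across the 3322 IDR peaks with a peak in both replicates, which are not independent replicates of each other, Spearman's rho of the signals was 0.845. Replicate 2 over replicate 1 had a median log2 ratio of 0.26 with an SD of 0.59 across peaks. As the scale of the signal and the depth are not known, this offset cannot be interpreted.

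**Figure D1:**
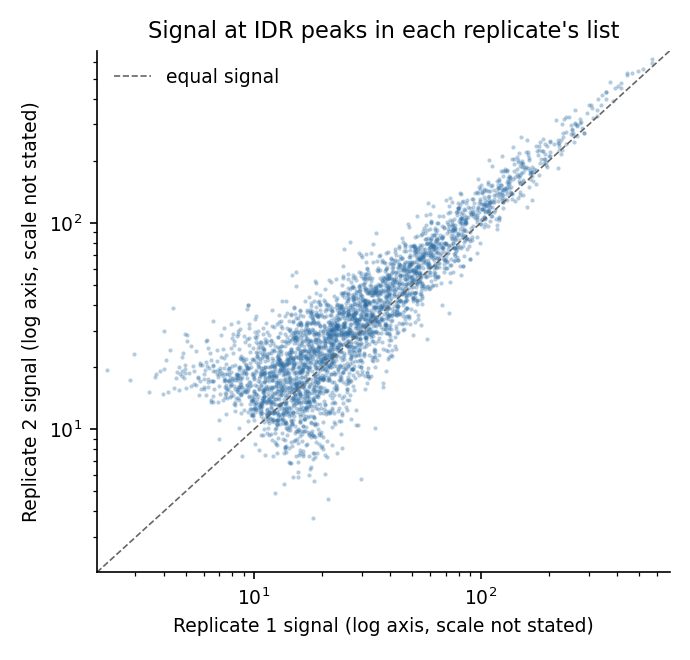
Signal of the authors' caller in the list of replicate 1 (x axis) and of replicate 2 (y axis), both on log axes with a scale that is not given; each point is 1 of 3322 IDR peaks and the dashed line marks equal signal. The signals rose together across peaks, with a Spearman's rho of 0.845.

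LIN-15B peaks lay mainly just upstream of genes. Each summit was counted once, in the first class that held it, and shifted summits were treated alike. The order was promoter window, 5' UTR, coding exon, 3' UTR, intron, non-coding gene and intergenic. The classes after the promoter window thus cover only sequence outside all promoter windows. Of the 3331 summits, 2098 (63.0%, 95% interval 61.3 to 64.6) were in promoter windows, 3.86-fold the 16.3% of shifted summits. Coding exons held only 5 summits (0.150%) against 21% for shifted summits, and introns held 384 (11.5%) against 31.0%. The 3' UTRs held 20 summits (0.600% against 2.76%) and intergenic sequence held 705 (21.2% against 24.9%). For each of these differences the permutation p from the shifts was 0.000999, the smallest they can give. The 5 in coding exons, chosen after their values were seen, were in rhgf-3, in ncl-1 and the overlapping ZK112.4, in nrfl-1, in swt-5 and in mom-1. The 5' UTRs (17 summits, permutation p = 1) and non-coding genes (102 summits, p = 0.178) did not pass the threshold. Non-coding genes did pass in the permutation test with windows of 1000 bp (0.669-fold, p = 0.002) and 200 bp upstream (1.32-fold, p = 0.003), in opposite directions, and in the stricter list (0.496-fold, p = 0.000999). The median distance to the nearest 5' end was 270 bp, against 1325 bp after shifting, and 82.8% of summits were upstream. With a window of 200 bp upstream, the promoter share was 39.4%, and intergenic summits were then 1.38-fold more frequent than after shifting.

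**Figure D2:**
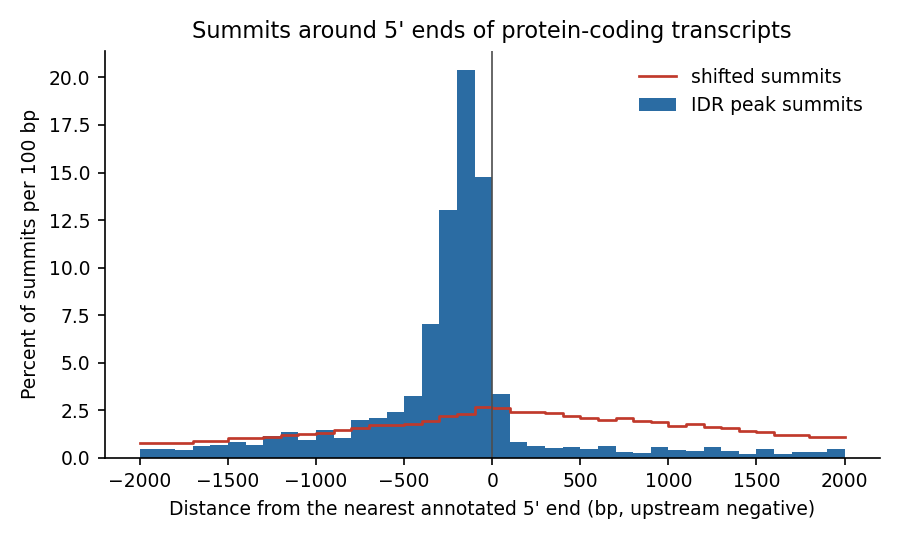
Percent of summits per 100 bp (y axis) by distance from the nearest annotated 5' end in bp (x axis, upstream negative); bars are the 3331 IDR summits and the line is the mean of 20 circular shifts. Of all summits, 82.8% lie upstream, against 43.2% after shifting.

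Many of the highest peaks stood at promoters of genes for protein synthesis. All 20 lay in promoter windows, which named 31 genes, and 10 of the 20 were at a ribosomal protein gene. The highest, with a signal of 1189 (II:10563413 to 10563745, ce11), lay upstream of cdc-48.1, an AAA ATPase that extracts ubiquitinated proteins. It was followed by peaks at rpl-20 and its neighbour Y17G9B.5 (1164, IV:4749893 to 4750241), at hsp-90, a chaperone, and C47E8.4 (1072), at iff-2, which encodes the translation factor eIF5A (1032), and at rpl-3 (992.4). The next were at tasp-1 (975.8), at ska-3 and rps-12 (960.8), and at rps-20 and ekl-4 (883.1). Each of these peaks was also present in both replicates. Other ribosomal protein genes among the 20 were rps-19 (peak shared with hsr-9), rpl-12 (with lin-54), rpl-35, rps-4, rpl-33 (with farl-11) and rpl-15 (with K11H12.8). A peak shared by vha-8, a subunit of the vacuolar proton pump, and C17H12.2 was also there.

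Across the genome 2683 of 19973 protein-coding genes (13.4%) were bound. Of the 18 gene lists, 5 were bound more often than other genes, 4 less often, and 9 did not pass the adjusted threshold. Ribosomal protein genes were bound in 67 of 78 cases (85.9%, 95% interval 76.2 to 92.7, adjusted p = 2.87e-46 by Fisher's exact test). Proteasome subunit genes were bound in 28 of 33 (84.8%, 68.1 to 94.9, adjusted p = 2.46e-19, exact test), with rpn-3 (653.8), rpn-9 (385.9), rpt-2 (345.8) and pas-4 (278.0) at the highest signals. The ribosomal call rested on the window. Of the 67 bound genes, 58 had their summit over 200 bp upstream, and the median position was -287 bp, against -176 bp for all bound genes. With a window of 200 bp upstream 9 of 78 (11.5%) were bound, against 7.59% of all genes, a difference from other genes of 3.96 points that did not pass the threshold (exact test, adjusted p = 0.349, range over its 9 alternatives 4.27e-55 to 0.349).

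Genes of the cell cycle and DNA replication were bound in 25 of 41 cases (61.0%, 44.5 to 75.8, exact test, adjusted p = 7.54e-12). The highest signals were at cdc-6 (412.5) and mcm-2 (122.8), which license replication origins, at pcn-1 (276.5), the sliding clamp, and at mdf-2 (186.1) of the spindle checkpoint. The synMuv B, DREAM and heterochromatin genes, the group LIN-15B itself belongs to, were bound in 10 of 18 cases (55.6%, 30.8 to 78.5, exact test, adjusted p = 7.55e-05). Bound members were lin-54 (840.2), lin-9 (529.9), lin-35 (321.8; I:5807320 to 5807663), the retinoblastoma homologue, lin-53 (303.7), efl-1 (257.4), an E2F factor, lin-36 (143.1), lin-15B (95.8), lin-61 (82.3), mep-1 (79.6) and dpl-1 (68.9). The lin-54 peak also lies in the promoter window of rpl-12, and the lin-61 peak in that of bub-1 (named after its value was seen), so neither can be assigned to 1 gene. The lin-15B peak could come from copies in the transgene, which was not tested. Not bound were lin-65, lin-37, lin-13, met-2, lin-52, hpl-2, tam-1 and let-418. With a window of 200 bp upstream 3 of 18 were bound (lin-9, lin-35 and efl-1) and the call was lost (exact test, adjusted p = 0.337, range over its 9 alternatives 1.65e-06 to 0.337).

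Small RNA pathway genes were bound in 12 of 45 cases (26.7%, 14.6 to 41.9, exact test, adjusted p = 0.0337), led by mut-15 (462.7), rde-4 (253.9), nrde-4 (142.5) and rrf-3 (140.2). This call by the exact test was lost with replicate 2's list alone (adjusted p = 0.0776), with replicate 1's list alone (0.0825), with a window of 200 bp upstream (0.595) and against genes with a letters-and-number symbol (0.167). Over its 9 alternatives the adjusted p ranged from 0.000901 to 0.595.

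Several large gene families were rarely bound. Chemoreceptor genes were bound in 9 of 1364 cases (0.660%, adjusted p = 3.39e-72), cuticle collagens in 3 of 156 (1.92%, adjusted p = 2.21e-06), nuclear hormone receptors in 11 of 269 (4.09%, adjusted p = 1.79e-06) and major sperm proteins in 0 of 31 (up to 9.68% allowed, adjusted p = 0.0341), all by Fisher's exact test. The bound collagens were col-38, col-71 and col-2. Peaks shifted at random, which seldom hit any promoter, bound a mean of 26.7 chemoreceptor genes, more than the 9 observed (permutation test, adjusted p = 0.00225). They bound 3.74 collagen genes (adjusted p = 0.938), 0.691 sperm protein genes (0.802) and 6.39 nuclear hormone receptor genes (0.130) in the same permutation test. The collagens and receptors were thus low against other genes but not against random positions. For the sperm proteins the shifts bound too few genes for a count of 0 to pass. Over their 9 alternatives the adjusted p of the exact or permutation tests ranged from 4.08e-09 to 0.938 for collagens and from 1.94e-10 to 0.130 for the receptors. The sperm protein call was lost in 6 of its 9 alternatives, including each replicate's list alone (exact test, adjusted p 0.0640 and 0.0625). Over these 9 the adjusted p of the exact or permutation tests ranged from 0.0127 to 0.802.

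Of the lists that did not pass, germ granule genes were bound in 0 of 16 cases (exact test, adjusted p = 0.229, up to 18.8% allowed) and intestinal genes in 0 of 20 (adjusted p = 0.177, up to 15% allowed). Both are too small for a count of 0 to pass. Unbound germ granule genes included pgl-1, pgl-3, glh-1 and deps-1. Meiosis genes were bound in 3 of 32 cases (brc-1, rad-51 and syp-2), and synMuv A genes in 1 of 4 (lin-38, 355.1), with lin-8, lin-56 and lin-15A not bound. Vulval induction genes were bound in 5 of 20 (sur-2, lin-25, lin-45, pop-1 and, chosen after its value was seen, egl-17), muscle genes in 2 of 18 (unc-112 and unc-89), neuronal genes in 3 of 20 (egl-21, rgef-1 and snb-1), histones in 13 of 80 (highest at his-37, 279.3) and homeobox genes in 4 of 63 (ceh-38, ceh-39, ceh-93 and ceh-74). The vulval list passed with a window of 200 bp upstream (exact test, adjusted p = 0.0445) and, like the histones, against shifted peaks (permutation test, adjusted p = 0.00225). Over its alternatives the adjusted p of the exact or permutation tests ranged from 0.00225 to 0.890 for the vulval list. For the histones that range was 0.00225 to 1. The homeobox list was lower against genes with a letters-and-number symbol (exact test, adjusted p = 0.0368, range 0.0368 to 0.810).

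**Figure D3:**
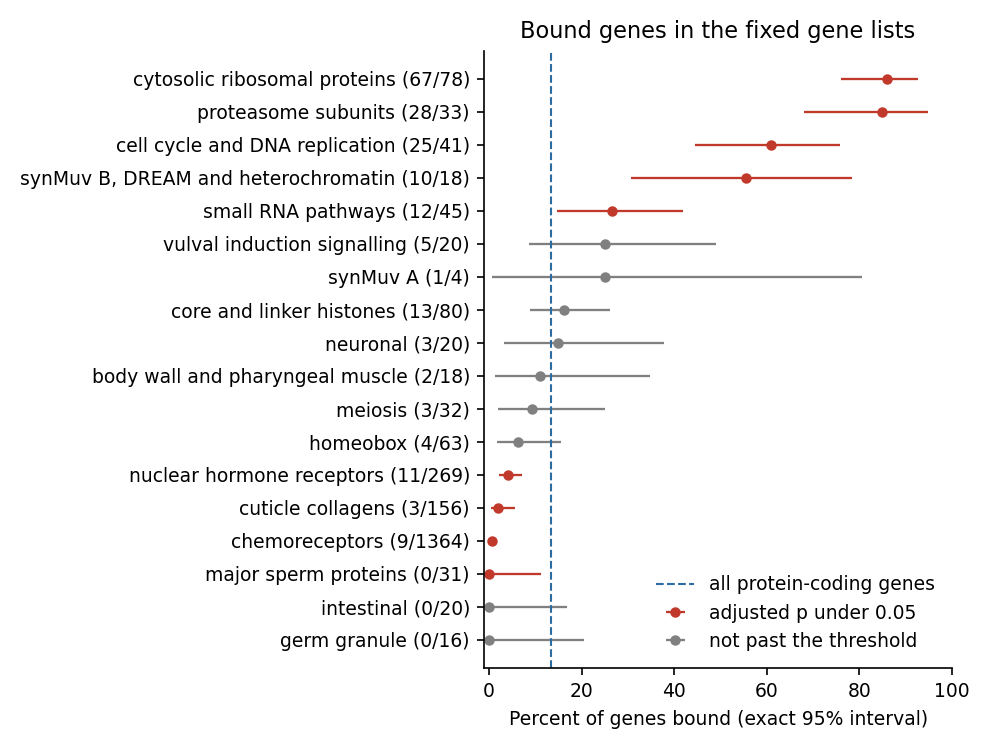
Percent of genes bound (x axis) in each of 18 lists, with exact 95% intervals, coloured by whether the adjusted p passed the threshold; the dashed line is the 13.4% of all protein-coding genes. Ribosomal proteins (85.9%) and proteasome subunits (84.8%) lie far to the right, and with a window of 200 bp upstream, not drawn here, the ribosomal list (11.5%, against 7.59% of all genes) did not pass the threshold.

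Bound genes were unevenly spread over the chromosomes. Chromosomes III (21.9%) and I (21%) had the highest shares of bound genes, followed by IV (13.8%), II (12.5%), V (8.29%) and X (7.36%). On X 201 of 2731 genes were bound, against 2482 of 17242 (14.4%) on the autosomes, a difference of -7.04 points (Fisher's exact test, p = 1.42e-26). In tests chosen after seeing the shares, X differed from V by -0.930 points over all genes, which did not pass the threshold (exact test, p = 0.159). Without the chemoreceptors, collagens, sperm proteins and nuclear hormone receptors X was lower than V by a difference of -2.87 points (exact test, p = 7.32e-05). The deficit against the autosomes was -4.64 points with a window of 200 bp upstream. On the autosomes, genes in the chromosome centres were bound more often (16.1%) than those in the arms (12.3%), by 3.75 points (exact test, p = 2.66e-12). That difference was 1.43 points with the window of 200 bp upstream and 1.74 points in the stricter list.

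**Figure D4:**
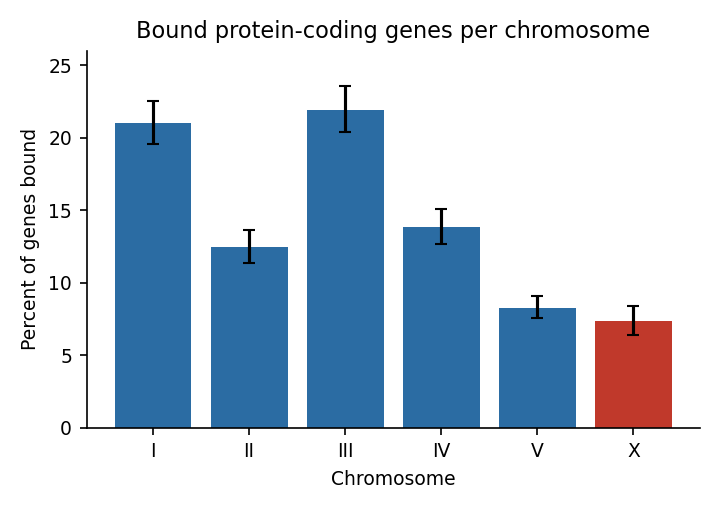
Percent of protein-coding genes bound (y axis) on each chromosome (x axis), with exact 95% intervals as error bars; X is in red. The intervals of V (7.54 to 9.09) and X (6.41 to 8.40) overlap, and those of I and III lie above the rest.

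The strongest peaks were the most often at promoters. The peaks were ranked by signal into 5 groups of nearly equal size. In the highest group 574 of 667 summits (86.1%, 83.2 to 88.6) were in promoter windows, and the next groups had 72.5%, 64.3% and 47.4%. In the lowest group it was 297 of 666 (44.6%, 40.8 to 48.5), 41.5 points below the highest (Fisher's exact test, p = 1.44e-59). The gap was 24.2 points with a window of 200 bp upstream and 27 points within the stricter list.

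Summit sequences were rich in G and C. The GC content within 50 bp of a summit was 47% ± 7.30 (SD across 3331 windows), against 34.9% ± 8.23 in the flanks. GAGA repeats were found at 26.9% of summits and 5.34% of flanks (exact sign test, adjusted p = 1.54e-127), E2F sites at 13.1% and 3.72% (adjusted p = 1.51e-44), GC boxes at 5.97% and 1.80% (adjusted p = 5.48e-19) and E-boxes at 3.06% and 1.53% (adjusted p = 3.57e-05). Less frequent at summits were TATA (3.78% and 12.7%), poly-T (4.83% and 11.6%), GATA sites (12.2% and 21.3%), the CHR element (18.9% and 28.3%) and the LIN-54 site (29.5% and 45.3%), all past the adjusted threshold by the exact sign test. Against summit windows shuffled with their dinucleotides kept, a control chosen after seeing the data, the CHR element and the LIN-54 site were instead more frequent at summits (ratios 1.41 and 1.33). With that control GAGA repeats fell from a ratio of 5.02 to 2.27, E2F sites from 3.51 to 1.58 and GC boxes from 3.30 to 1.95, all still past the threshold, while TATA, poly-T, GATA and E-boxes did not differ past it. Against unbound promoters, also chosen after seeing the data, the ratio was 2.84 for GAGA repeats, 2.03 for GC boxes and 4.37 for E2F sites. With windows reaching 100 bp to each side of the summit TATA moved from 0.299 to 0.588 and poly-T from 0.417 to 0.706. Of 2080 6-mers, 762 were more and 640 less frequent at summits than in flanks, against 379 and 699 with shuffled windows. The 5 with the highest ratios were GCGCGC (12.7), ACGCGC (12.4), AGCGCG (12.1), GAGCGC (11.6) and CGGCCG (10.6). With windows reaching 100 bp to each side of the summit these ratios were from 4.26 to 8.13. CGGCCG, found in only 12 flanks, had a ratio of 6.64 without replicate 2 and 4.65 with flanks 600 bp away, and GCGCGC had 19.95 in the stricter list.

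**Figure D5:**
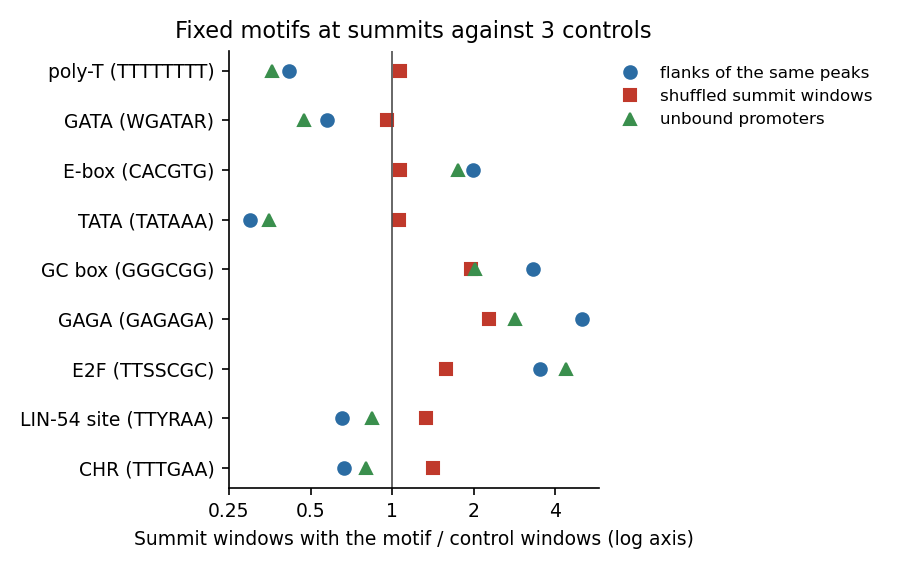
Summit windows with a motif over control windows with it (x axis, log axis) for 9 fixed motifs (y axis), against flanks of the same peaks, shuffled summit windows and unbound promoters; the line marks a ratio of 1. GAGA, E2F, GC box and E-box lie above 1 with every control, the E-box not past the threshold against shuffled windows (1.07). CHR (0.667, 1.41 and 0.802) and the LIN-54 site (0.652, 1.33 and 0.842) cross the line. TATA (0.299, 1.06 and 0.352) and poly-T (0.417, 1.07 and 0.359) also cross it, but not past the threshold against shuffled windows.

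The loci used to build the transgene were examined because extra copies could give signal of their own. Within 40000 bp of lin-15B (X:15686123 to 15772025, ce11) there were 6 IDR peaks where the density of X gives 1.66, and 0.907% of windows of that width on X held as many. The pooled list held 26 where its density gives 24.6. The list of replicate 1 held 22 against 19.8 by density, and that of replicate 2 held 34 against 23.2. As many were found in 39.0% and 6.63% of windows on X. The highest IDR peak (X:15725043 to 15725310, rank 69, signal 425.9) was intergenic, and the lin-15B promoter window held a peak of rank 867, 357 bp upstream of the 5' end. Within 40000 bp of unc-119 on chromosome III there were also 6, where 4.34 would be given by density and 29.7% of windows held as many. Of these, a pair had summits in introns of unc-119 itself (III:10903388, rank 2651, and III:10905357, rank 2806). The promoter windows of unc-119 and lin-15A held no IDR summit. The annotated lin-15A gene starts at X:15731968, inside lin-15B, which ends at X:15732025 on the same strand. Its window there covers the end of lin-15B and may not hold the site of initiation of lin-15A.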

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

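The results in this paragraph are signals in the pooled list, which the main comparisons of bound genes did not use, and these tests were chosen after the results of those comparisons were seen. No germ granule gene was bound in the IDR list, yet 31.3% of the 16 had a pooled-list peak in the promoter window (95% interval 11 to 58.7; glh-1, znfx-1, ife-1, meg-1 and meg-2), against the 18.8% that a count of 0 allows in the IDR list. For the 20 intestinal genes the value was 25% (8.66 to 49.1; act-5, lys-4, elt-7, cpr-1 and cpr-6), against the 15% allowed. These genes were chosen after their values were seen. Both intervals include the level allowed, and the pooled list is far longer than the IDR list, so an excess is not shown. Neither share was above that of the genome, where 36.8% of all protein-coding genes had such a peak. The germ granule gene znfx-1 had the pooled peak of rank 3332, the first below the IDR list, with a signal of 22.6. The other germ granule genes with such a peak ranked from 13467 (ife-1, 5.95) to 29150 (glh-1, 3.37). The pooled list was deposited as peaks and background, so these entries may be background. No explanation was tested for these values.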

How the results depend on the processing

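Feature classes, transgene loci, the lenient list, and the shuffled and unbound-promoter controls were run under alternatives chosen after seeing the data. The peak number (2722 to 4585), replicate agreement (75.3% to 86.3%), promoter share (39.4% to 76.1%), X deficit (-8.10 to -4.64 points), centre excess (1.43 to 4.96 points) and signal gap (24.2 to 46.8 points) kept their direction and their side of the threshold, or for the peak number stayed within 1.5-fold, in every alternative run. Tested values were taken as unchanged if they kept direction and side of the threshold. Counts of peaks, of passing lists, of 6-mers and of named genes were taken as unchanged within 1.5-fold. Counting each alternative of each result, 99 of 110 for the main results and 209 of 248 for single lists, motifs, the 9-mer and named genes were unchanged. Among the latter 15 kept their direction but no longer passed and 4 newly passed. Between 6 and 9 gene lists passed, and the cell cycle, proteasome and chemoreceptor lists passed in all 9 alternatives.

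Relative to shifted summits, 5' UTRs moved from 1.02 to 0.865 in the lenient list, 0.886 with a window of 1000 bp upstream and 0.593 in the stricter list, and from 0.95 to 1.01 with 1 replicate left out. None of these passed the threshold. Non-coding genes moved from 0.870 to 1.07 in the lenient list and, past the threshold, to 0.669 with 1000 bp, 1.32 with 200 bp and 0.496 in the stricter list. Intergenic summits went from 0.850 to 1.38 with 200 bp, where the narrower window itself passes summits to this class. The stricter list left 3 peaks near unc-119. Shuffled windows left 379 6-mers more frequent and reversed the CHR element (1.41), the LIN-54 site (1.33), TATA (1.06) and poly-T (1.07), the last pair not past the threshold. Shuffling keeps base composition, which flanks do not.

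Lists that changed direction without passing were, in points: against shifted peaks, muscle 6.23, homeobox 3.67, meiosis 6.19 and nuclear hormone receptors 1.71; against letters-and-number symbols, histones -1.04 and neuronal -2.29; in the stricter list, histones -3.54 and neuronal -3.53; in the lenient list, muscle 0.736 and neuronal -0.932; with 200 bp, neuronal -2.59 and synMuv A -7.59; with windows counted once, meiosis 0.986; with 1 replicate left out, histones -3.04 to -0.766. Apart from the window and control effects named, the cause was not tested. Of 78 named genes, 76 were bound with either replicate left out and 42 with 200 bp upstream. Depth is unknown, so the effect of sequencing more reads could not be examined.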

Other observations

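The counts by gene class, symbol group, gene orientation and 9-mer, the tests on tRNA genes, over all GC-rich 6-mers, of X against V and of X over more ranks were chosen after the results were seen. Among non-coding genes, LIN-15B was at the promoter windows of 92 of 346 snoRNA genes (26.6%, 95% interval 22 to 31.6) and 105 of 612 tRNA genes (17.2%, 14.3 to 20.4), but at 74 of 15363 piRNA genes (0.482%) and 29 of 2128 pseudogenes (1.36%). Counting only summits outside the promoter windows of protein-coding genes, the shares were 17.3% for snoRNA, 13.9% for tRNA, 0.267% for piRNA genes and 0.846% for pseudogenes. Genes outside the fixed lists were also grouped by the letters of their symbol, which joins gene families but also genes named for a shared phenotype, such as unc. Of 207 such groups with at least 8 members, 25 were bound more and 14 less often than other genes after adjustment by Fisher's exact test. Higher ones included nuclear pore proteins (npp, 20 of 26), translation initiation factors (eif, 19 of 25), RNA polymerase II subunits (rpb, 9 of 11), Integrator subunits (ints, 9 of 11) and chaperonin subunits (cct, 7 of 8). Lower ones included the ugt family of glucuronosyltransferases (0 of 67) and the transthyretin-related ttr family (0 of 58). Gaps between divergent genes held 107 summits per Mb, tandem gaps 53.5 and convergent gaps 13.6.

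The sequence CTGCGTCTC is a known core promoter sequence of C. elegans, chosen after the 6-mers were seen and not built from them. It was within 50 bp of 372 of 3331 summits (11.2%) and in 10 flanks (0.30%), a ratio of 35.5 (exact sign test, p = 3.19e-98). The ratio was 49.7 against shuffled windows and 11.1 against unbound promoters, of which 0.858% held it. The ratio rested on few control windows and was 19.6 without replicate 2 (343 against 17 windows). It was 18.8 with windows reaching 100 bp to each side of the summit and 21.2 in the lenient list.

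Ribosomal protein and proteasome promoters were bound in 95 of 111 cases (85.6%). Signal spread along highly transcribed genes was not seen as separate peaks in the bodies of these genes. The density of summits there was 0 times that in their windows (0 summits in 71533 bases, which allows up to 0.0380). Spread without a summit of its own could not be examined, because a summit marks only the top of a peak. Coding exons outside promoter windows held few summits in any gene (5 of 3331), so the count of 0 cannot argue against such spread. GC content of the whole promoter window is argued against, as other genes weighted to the same window GC were bound at 15.4% (bootstrap SE 0.306). GC close to the summits was not weighted for and stays open. It was 46.4% within 50 bp of promoter summits, against 34.8% at the same distance in unbound promoters. Promoters that any immunoprecipitation enriches remain a possible explanation: the 17.2% of tRNA genes bound (14.3 to 20.4) was above the 13.4% of all coding genes and below the 42.8% set for that explanation, and 13.9% without summits in coding promoter windows, but tRNA genes are another class of promoter and no control profile was analysed here. The design gives no second group, so no biological explanation was tested.

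X genes were bound less often than autosomal genes. Chemoreceptors, collagens, sperm proteins and nuclear hormone receptors are argued against as the cause, since the difference was 8.36 points without these 4 families. They are few on X, where 2648 of 2731 genes remained, so taking them out could hardly shrink the difference. Other rarely bound families were not taken out, so families in general stay open. GC of the whole promoter window is argued against, since autosomal genes weighted to the window GC of X genes were bound at 15.3% against 7.36%. GC close to the summits was not weighted for. Whether the threshold contributes cannot be told. Among promoter peaks in the next band of ranks, 3332 to 6662 of the pooled list, 16.6% were on X (14.4 to 19.0), above the 13.7% of genes there. However, the genes already bound were mostly autosomal, which raises the X share of those left. Background entries could give such a share too, as X held 5064 of the 30000 pooled entries. The deficit shrank from -7.04 points to -5.81 with those ranks added and to -2.25 (exact test, p = 0.0236) over the whole pooled list, so it was smaller but still present when weaker peaks were counted, and X and V differed by -0.930 points over all genes (exact test, p = 0.159) but by -2.87 without the 4 families (p = 7.32e-05). No biological explanation was tested.

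GC-rich 6-mers were more frequent at summits. A sequence shared by all promoters, bound or not, is argued against. The median ratio of the top 5 was 14.8 against unbound promoters, though these 6-mers were picked on the same summit windows. The GC content, which was not picked, was 46.4% at promoter summits against 34.8% at the same distance in unbound promoters. The unbound genes were drawn at random, whether active or not. A sequence shared only by active promoters therefore stays open. How much of the excess comes from base composition cannot be told. The median of the top 5 fell from 12.1 against flanks to 2.07 against shuffled windows (1.85 to 2.77). Shuffling keeps the dinucleotides of each summit window, including those of the 6-mers themselves, and so can rebuild them. A fall could follow whether or not base composition is the cause. Dinucleotide content alone did not give the frequencies at summits, as of all 2080 6-mers 379 were more and 699 less frequent than in shuffled windows. Of 512 GC-rich 6-mers 30.9% were more and 12.5% less frequent, but they were picked on the same windows. Whether base composition is the whole cause of the excess over flanks stays open. Other 6-mers differed from shuffling too, and the flanks were not shuffled for comparison. No biological explanation was tested.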
